A study of Sus scrofa with 207 samples.

How the data were processed

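Muscle of 207 crossbred pigs, taken at slaughter at a mean end weight of 110 kg, was profiled by the authors on Affymetrix Porcine Genome Arrays, 1 per animal, from total RNA isolated with TRI Reagent, treated with DNase and labelled as biotinylated cRNA. Per the submitters' processing notes the arrays were processed with GCOS 1.1.1 and summarised with PLIER; no further normalization, filter or correction is stated. The deposited values are log2 expression values per probe set, from 4.00 to 15.32, with a floor at 4 that equals 16 on the linear scale and holds 1.43% of the values. Array medians lay between 5.96 and 6.18; whether the arrays were scaled to each other is not stated. The deposited log2 values were used as they stand, without renormalization. The 2 traits of each animal, fat area in cm2 and drip loss in percent, came from the labels. The labels as used here give no sex, sire, slaughter day or array batch, so none of these entered a fit.

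Of 24123 probe sets, 188 controls were left out and 23935 were tested. Gene symbols came from the array annotation: 10069 tested probe sets carried exactly 1 symbol, 198 several and 13668 none. Of the single-symbol probe sets 9961 matched the reference gene table by gene number, with 0 symbols changed, and that table, made for another purpose than this array, gave only the chromosome of a gene. For tests on genes and gene lists, 1 probe set stood for each of 6765 genes, the one with the highest mean over the 207 arrays.

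Each probe set was regressed on a trait scaled to SD 1 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, so that slopes are log2 units per SD of the trait (SD 3.15 cm2 and 2.22%), and adjusted by the Benjamini-Hochberg method over all tested probe sets with a threshold of 0.05, two-sided. A further fit held both traits, in the 207 animals less the 8 without a fat area, and tested the difference of the slopes. Gene lists were tested by camera with the preset inter-gene correlation of 0.01, two-sided and adjusted over the 34 lists with at least 5 measured genes; camera with an estimated correlation and the directional p of fry were computed beside it. The 36 lists covered lipid and energy metabolism, fibre types and muscle structure, protein turnover, stress and signalling, and markers of other cell types; nerve and Schwann cell markers (4 measured) and sex chromosome-linked genes (2 measured) were too few to test as lists. Of the nerve and Schwann cell markers, 0 passed for either trait in limma over all genes. Within a list, members were counted as passing over all 6765 genes and when adjusted over the list alone. In the list counts 3 genes stood in more than 1 list. Correlations with list means used 100000 permutations of the trait, 20000 within blocks or number series and 10000 for array properties.

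The lists, the tests, the traits and the rule for named genes were fixed before the data were examined. The rule took, per trait, the 12 probe sets with the largest positive and the 12 with the largest negative moderated t among those with an adjusted p under 0.05, exactly 1 gene symbol, a mean above the median of all tested probe sets (6.10) and a Spearman rho of the same sign, and all that passed where there were fewer than 12. It added the 3 members with the smallest p, moving in the list's direction, of each list called by camera. For the difference between the traits it took 5 in each direction. FABP4, ADIPOQ, SCD, FASN, MYH7, MYH4, PRKAG3, RYR1, CAST and PYGM were given whatever their values, and MYH4 was not measured by a probe set with a single symbol. For fat area 2 increases and 7 decreases met the conditions, and for drip loss 267 and 145 did.

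Alternatives changed 1 choice at a time: quantile normalization, only probe sets with a mean above that median, the number series or the blocks of 100 title numbers as a covariate, either number series alone, the first 5 principal components, normal scores of the trait, without the 2 animals farthest from the trait median, without the arrays whose median correlation lay over 3 scaled MAD below that of all arrays, the other trait, the first principal component of EIF1AY and SRY or the adipocyte marker mean as a covariate, eBayes with trend and robust, and, for lists, the mean of all probe sets of a gene. After seeing the data, 2 more were added: the difference between the 3' and 5' signals of the actin and EF1A controls as a covariate, and leaving out the 13 arrays whose spike-in signal stayed at or below 4.28, against 6.47 or more in all others. The log2(value + 1) alternative was not run, since it applies to linear values only. As a check on chance, each trait was assigned at random to the animals 100 times, the real assignment included.

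The pipeline was tested on simulated data with 50 probe sets raised or lowered at each of 4 sizes among 23935. For fat area it recovered 40% at 0.05 log2 per SD, 92% at 0.1, 100% at 0.2 and 100% at 0.4, and for drip loss 42%, 90%, 100% and 100%, with 6 and 5 false calls. A simulated rise of 0.1 in complex I was recovered by all list tests among 6765 genes; camera with the preset correlation also called 6 other lists for fat area and 4 for drip loss, while camera with an estimated correlation and fry called 0 others.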

Results

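Gene expression was measured in muscle taken at slaughter from 207 crossbred pigs of 1 commercial herd, with 1 Affymetrix Porcine Genome Array per animal. The labels put every animal in a single group and give 2 traits, so each comparison is a regression of log2 expression on a trait and no animals were sorted into classes. Fat area, measured over the longissimus muscle, averaged 15.0 ± 3.15 cm2 (SD, n = 207 less 8 animals for which it was not given) and ranged from 8.1 to 26.7 cm2. Drip loss, the percentage of weight that a hung piece of longissimus muscle loses as fluid in the cold, averaged 5.37 ± 2.22% (SD, n = 207) and ranged from 1.45 to 10.82%. The arrays held 23935 probe sets that are not controls, of which 10069 carried exactly 1 gene symbol and stood for 6765 genes. Array medians lay between 5.96 and 6.18 on the log2 scale, and the number of arrays limits the precision of every slope. For 24 arrays the median correlation with the other arrays was low, down to 0.944 against a typical 0.978. Another 13 arrays lacked the signal of the poly-A spike-in controls. The animals behind the 24 low-correlation arrays had a drip loss of 4.20 ± 1.55% (SD, n = 24) against 5.53 ± 2.25% (SD) in all others (permutation p = 0.0059, adjusted p = 0.059 over 10 such relations, two-sided). The numbers in the sample titles form 2 series with a gap between them, a lower one and a higher one that holds 33 animals. Grouping the numbers into 10 blocks of 100 numbers accounted for 8.78% of the variance of drip loss, 6.98% of that of fat area and 17.9% of that of the first principal component of expression.

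Fat area and drip loss were nearly unrelated in these animals. Pearson's r was -0.094 (permutation p = 0.184, two-sided) and Spearman's rho was -0.072 (permutation p = 0.315) over the animals with both values, with this single pair of traits in its family. Without the 2 animals whose fat area lay farthest from the median, r was -0.089. It was -0.062 in the lower number series, -0.25 in the higher (n = 25) and -0.098 with both traits centred within blocks.

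Muscle of pigs with higher drip loss, that is, with meat that held its water less well, carried less mRNA of the immediate early genes, which cells switch on rapidly after a stimulus. Of 18 measured members of this list, 14 fell with drip loss when adjusted over all 6765 genes and 16 when adjusted over the list alone, and 18 had a negative slope. The transcription factor FOS fell by 0.49 ± 0.078 on the log2 scale per SD of drip loss (SE, n = 207, limma adjusted p = 7.6e-06), a change of -28.8% per SD. EGR1, another rapidly induced transcription factor, fell by 0.42 ± 0.067 (adjusted p = 9.5e-06), the matricellular CYR61 by 0.34 ± 0.050 (adjusted p = 8.9e-07) and the MAP kinase phosphatase DUSP1 by 0.27 ± 0.039 (adjusted p = 4.8e-07). Transcripts of the mitochondrial respiratory chain went the other way, and 16 of 33 measured subunits of complex I, the NADH dehydrogenase, rose with drip loss. With blocks in the fit 1 rose, without the low-correlation arrays 2 did, and camera did not call the list with an estimated correlation (adjusted p = 0.191).

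Among the single genes that passed the test, the chemokine CXCL2 had the smallest adjusted p. It fell by 0.30 ± 0.042 per SD of drip loss (SE, n = 207, adjusted p = 3.1e-07). Other strong decreases among the named genes were those of the transcription factors MYC, which fell by 0.27 ± 0.050, and KLF4, which fell by 0.22 ± 0.043, and of ZFP36, which promotes decay of short-lived mRNAs and fell by 0.30 ± 0.061. The secreted glycoprotein THBS1 fell by 0.15 ± 0.027, the ERK phosphatase DUSP6 by 0.14 ± 0.025, the small GTPase RHOB by 0.14 ± 0.029 and the RNA-processing protein SON by 0.091 ± 0.019. The adjusted p values from MYC to SON lay between 1.7e-04, for THBS1, and 0.0015, for SON. Among the increases, ATP5I, a subunit of ATP synthase, rose by 0.10 ± 0.020 (adjusted p = 7.0e-04), the mitochondrial hydrolase ABHD10 by 0.087 ± 0.016 (adjusted p = 2.6e-04), the mitochondrial protease LONP1 by 0.049 ± 0.0099 (adjusted p = 9.9e-04) and the complex I subunit NDUFA2 by 0.065 ± 0.014 (adjusted p = 0.0021). The translation factor EEF1A1 rose by 0.053 ± 0.011 and CDK11B by 0.049 ± 0.010, both with an adjusted p of 0.0022. SWSAP1 rose by 0.092 ± 0.019, RANGRF by 0.082 ± 0.017, CIB1 by 0.077 ± 0.016, PIH1D1 by 0.068 ± 0.015, SLX1A by 0.066 ± 0.014 and LAMTOR5 by 0.049 ± 0.011. With blocks in the fit all of these increases still passed except that of RANGRF, at 0.054 ± 0.016 (adjusted p = 0.090). Of the 42 genes picked by the rule for named genes that passed for drip loss, 18 did not pass with blocks, 13 did not without the 24 low-correlation arrays and 36 did not with 5 principal components. The 6 that passed with principal components were CXCL2, DUSP1, DUSP6, CYR61, FOS and EGR1.

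The mean log2 value of the immediate early genes had a slope of -0.21 ± 0.033 per SD of drip loss (SE, n = 207). Its correlation with drip loss was r = -0.405 and rho = -0.398, each with a permutation p of 1e-05, the smallest that the permutations can give, and an adjusted p of 3.4e-04 over 34 lists. Without the 2 animals farthest from the median drip loss, r was -0.42. Inside the lower number series r was -0.375, inside the higher -0.531 (n = 33), and over the 10 blocks it ranged from -0.644 to 0.025 and was negative in 9. By camera the list fell against all other genes (adjusted p = 1.7e-28 with the preset correlation) and it was the only list still called with an estimated correlation (adjusted p = 0.0011). The members that did not pass over all genes were MCL1, IER5, ATF3 and SOCS3, with slopes of -0.055 ± 0.019, -0.11 ± 0.037, -0.13 ± 0.068 and -0.024 ± 0.016. Without the 24 low-correlation arrays the mean slope was -0.21 ± 0.035 and 11 members fell. With blocks in the fit it was -0.20 ± 0.034 and 12 fell, and with 5 principal components it was -0.10 ± 0.022 and 4 fell.

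**Figure D1:**
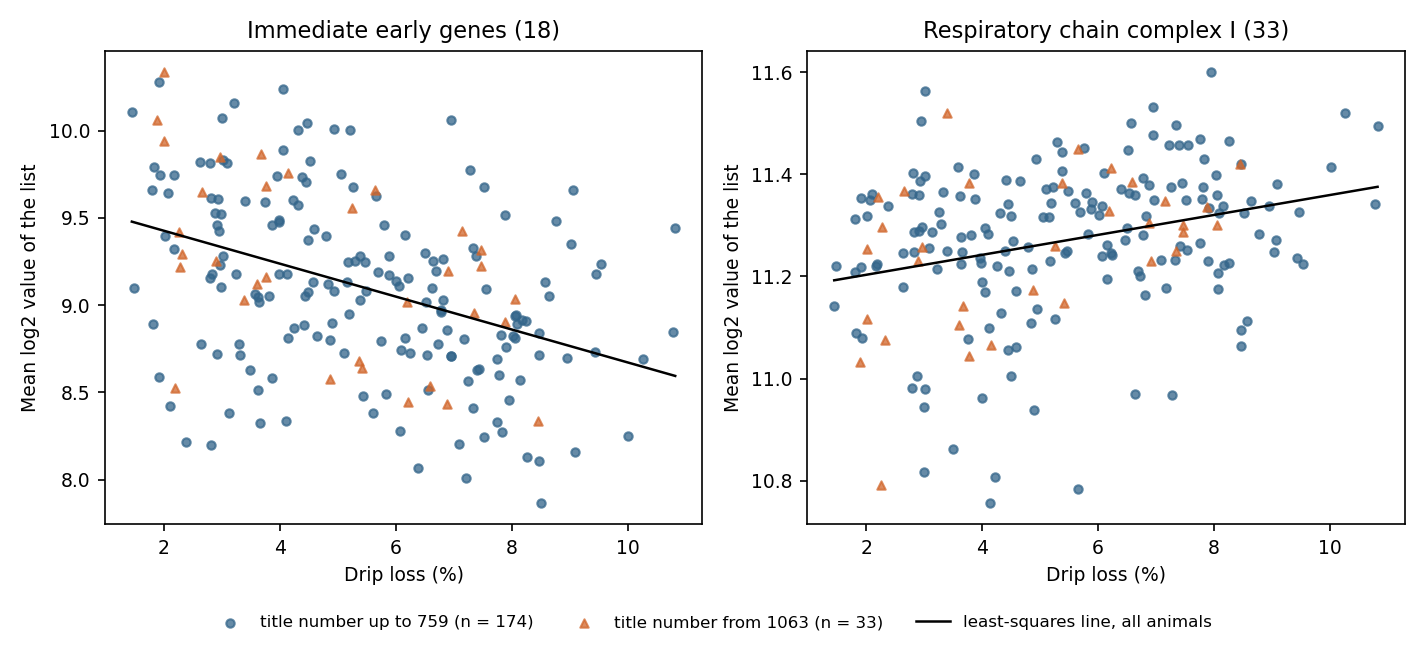
Mean log2 value of 18 immediate early genes (left) and 33 complex I subunits (right) in each animal against drip loss in percent, with circles for the lower number series, triangles for the higher (n = 33) and a least-squares line through all 207 animals. The first list declines with drip loss (r = -0.405) and the second climbs (r = 0.288), with wide scatter around both lines.

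All 33 complex I subunits had a positive slope, 16 rose when adjusted over all genes and 26 when adjusted over the list alone. NDUFA8 rose by 0.080 ± 0.019 per SD of drip loss (SE, n = 207, adjusted p = 0.0076) and NDUFB2 by 0.078 ± 0.018 (adjusted p = 0.0058). The list mean had a slope of 0.043 ± 0.010. Its r with drip loss was 0.288 (permutation p = 4e-05, adjusted p = 6.8e-04 over 34 lists) and its rho was 0.269 (permutation p = 1.3e-04). Without the 2 farthest animals r was 0.274, in the lower number series it was 0.258, in the higher 0.436, and over the blocks it ranged from -0.296 to 0.565 and was positive in 8 of 10. Camera called the list with the preset correlation only (adjusted p = 1.2e-12), while fry, which asks whether the members move on balance one way, called it (adjusted p = 4.3e-04). The rise was smaller with blocks in the fit or without the 24 low-correlation arrays. The mean slope was 0.032 ± 0.010 with blocks in the fit and 1 subunit rose, and it was 0.027 ± 0.0081 without those arrays and 2 rose. With both changes it was 0.017 ± 0.0081 and 0 passed in limma.

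Other energy and protein turnover lists went the same way in part. Of 14 measured subunits of complexes II to IV, 6 rose, among them COX7A2 by 0.067 ± 0.017 and COX6C by 0.056 ± 0.016 (SE, n = 207), and the list was called by camera at an adjusted p of 5.5e-06 (adjusted p = 0.237 with an estimated correlation). Of 15 ATP synthase genes 7 rose, with ATP5H at 0.057 ± 0.014 and ATP5L at 0.054 ± 0.013, again with an adjusted p of 0.237 with an estimated correlation. Without the 24 low-correlation arrays, 0 members of complexes II to IV and 1 of ATP synthase passed in limma, and with blocks in the fit the numbers were also 0 and 1. From the TCA cycle, SUCLG1, MDH1, PDHB and IDH3B made up the 4 of 18 that rose, and SUCLG1, a succinyl-CoA ligase subunit, did so by 0.043 ± 0.012. From the proteasome, PSMC3, PSMB7, PSMC5 and PSMD4 made up the 4 of 29 that rose, PSMC3 by 0.058 ± 0.014. The TCA cycle and proteasome lists were called by camera at adjusted p values of 0.033 and 0.0073, and had adjusted p values of 0.622 and 0.683 with an estimated correlation. In limma 0 TCA cycle genes and 1 proteasome gene passed with blocks in the fit. Without the 24 low-correlation arrays 0 and 2 did, and camera no longer called the TCA cycle (adjusted p = 0.26). Cytosolic ribosomal proteins were called upward (adjusted p = 0.0095, and 0.789 with an estimated correlation), with 50 of 57 slopes positive. They were not called with blocks in the fit (adjusted p = 0.586) or without those arrays (adjusted p = 0.233). With 5 principal components the list had a slope of the opposite sign, -0.0060, and a camera adjusted p of 0.0019. RPS18 (0.035 ± 0.015), RPL13A (0.031 ± 0.011) and RPL31 (0.028 ± 0.011) did not pass singly, and the 1 member that passed, a dim probe set for RPL30, fell by 0.094 ± 0.017.

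Besides the immediate early genes, camera called heat shock, hypoxia response, costamere and interferon response genes downward. Of 19 heat shock genes 3 fell, the cochaperones BAG3 by 0.099 ± 0.026 and DNAJB4 by 0.12 ± 0.042 and the chaperone HSPH1 by 0.15 ± 0.051 (SE, n = 207; camera adjusted p = 5.5e-06, adjusted p = 0.237 with an estimated correlation). Of 13 hypoxia response genes 3 fell, the vasodilator peptide ADM by 0.14 ± 0.030, the oxygen-regulated factor HIF1A by 0.11 ± 0.029 and the glucose transporter SLC2A1 by 0.072 ± 0.022 (camera adjusted p = 0.033, adjusted p = 0.191 with an estimated correlation). Of 20 costamere and cytoskeleton genes, the actin-binding XIRP1 and XIRP2 fell by 0.16 ± 0.052 and 0.089 ± 0.026, CAPZB rose by 0.057 ± 0.017, and VCL had a slope of -0.040 ± 0.017 that did not pass (camera adjusted p = 0.045, adjusted p = 0.513 with an estimated correlation). Of 16 interferon response genes IFIT1 alone fell, by 0.048 ± 0.015, while RSAD2 and USP18 had slopes of -0.089 ± 0.065 and -0.052 ± 0.043 (camera adjusted p = 0.045, adjusted p = 0.683 with an estimated correlation). With blocks in the fit, 0 heat shock, 1 hypoxia, 0 costamere and 0 interferon response genes passed in limma. The costamere list was then no longer called (camera adjusted p = 0.193). Without the 24 low-correlation arrays the numbers were 1, 2, 1 and 0. The interferon list was then no longer called (camera adjusted p = 0.0525).

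**Figure D2:**
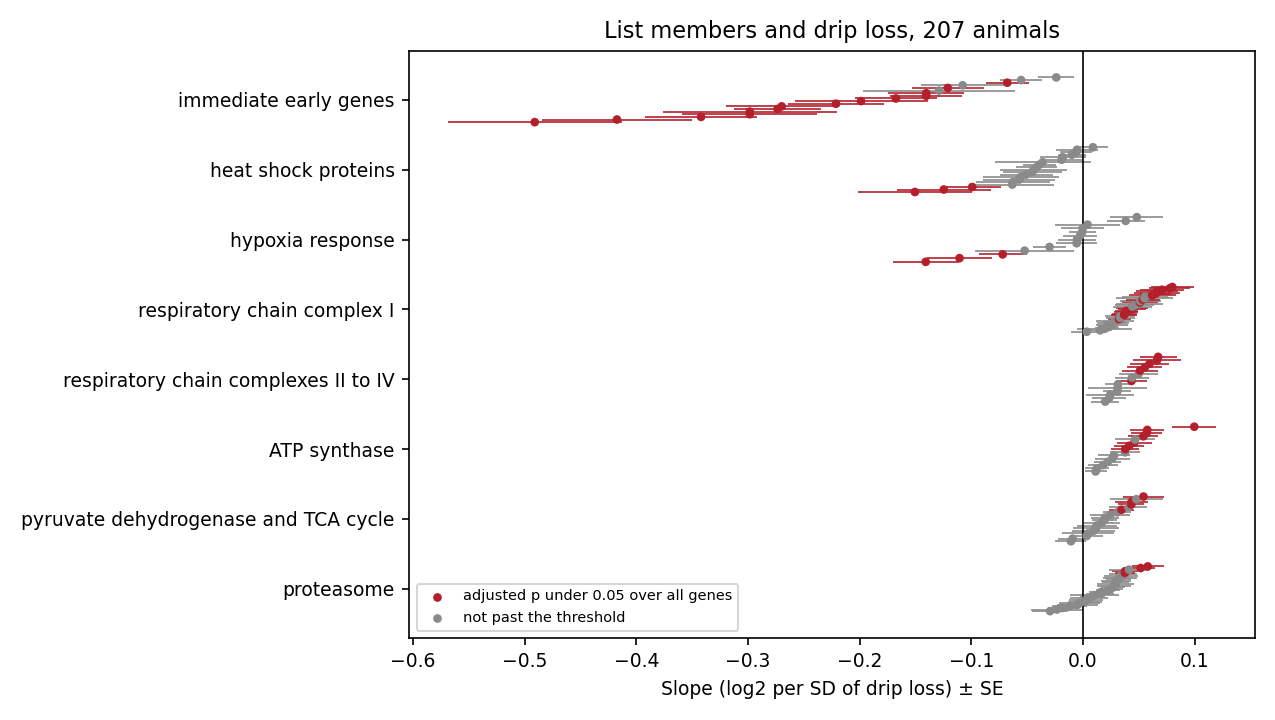
Slope of each measured member of 8 gene lists on drip loss, in log2 units per SD with bars of 1 SE, over 207 animals; red points passed an adjusted p of 0.05 over all 6765 genes and grey points did not. Immediate early genes reach from FOS at -0.49 to SOCS3 at -0.024, while all 33 complex I subunits lie right of 0.

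The other 23 lists were not called by camera (adjusted p 0.0704 to 0.953) and held 13 genes that passed. In 6 of them the camera direction, the median slope and the slope of the list mean did not share a sign. In them the clock-related repressor NFIL3 fell by 0.24 ± 0.060 (SE, n = 207), the mitochondrial coactivator PPARGC1A by 0.27 ± 0.087, the stress factor DDIT3 by 0.14 ± 0.047 and the endothelial ENG by 0.068 ± 0.022. The fatty acid oxidation enzyme ECI1 rose by 0.080 ± 0.020, the quinone reductase NQO1 by 0.086 ± 0.027, GCLC by 0.034 ± 0.010 and PRDX5 by 0.049 ± 0.016. The glycolysis genes TPI1 and GPD1 rose by 0.045 ± 0.014 and 0.042 ± 0.013, ATF4 by 0.041 ± 0.012 and the lymphocyte chemokine CCL5 by 0.076 ± 0.025. Of these genes only NFIL3 and NQO1 passed with blocks in the fit (both with an adjusted p of 0.040). In 15 lists no member passed in limma over all genes: slow and fast fibre, calcium handling, adipocyte, macrophage, blood cell and satellite cell markers, fatty acid and triglyceride synthesis, cholesterol synthesis, extracellular matrix, atrophy and autophagy, calpains with cathepsins and caspases, insulin signalling, branched-chain amino acid breakdown, and water and ion transport. Fry called 12 lists, of which 8 were also called by camera and 4 were not, namely lymphocyte markers, blood cell markers, circadian clock, and antioxidant and metallothionein. The fry calls of complexes II to IV, ATP synthase, TCA cycle, proteasome, heat shock, hypoxia response and antioxidant genes ended with blocks in the fit (adjusted p 0.055 to 0.125). Camera with blocks in the fit gained lymphocyte markers (adjusted p = 0.022), circadian clock (0.024), fatty acid and triglyceride synthesis (0.036) and extracellular matrix (0.042). With an estimated correlation these were not called (camera adjusted p 0.097 to 0.675). Among the lists not called by camera, the list mean correlated with drip loss for circadian clock (r = -0.257, adjusted permutation p = 0.0018), lymphocyte markers (r = 0.186, adjusted permutation p = 0.028) and water and ion transport (r = 0.179, adjusted permutation p = 0.031; rho = 0.163, adjusted permutation p = 0.060). Of the candidate genes for meat quality fixed beforehand, PRKAG3, the muscle AMPK subunit, rose by 0.055 ± 0.017 (adjusted p = 0.042; adjusted p = 0.077 with blocks). The calcium release channel RYR1 (-0.032 ± 0.013, adjusted p = 0.156), PYGM (0.0070 ± 0.0060), CAST (0.014 ± 0.013), MYH7 (-0.0036 ± 0.0074), FASN (-0.046 ± 0.059), FABP4 (0.025 ± 0.037), ADIPOQ (-0.022 ± 0.033) and SCD (0.0096 ± 0.083) did not pass.

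In total 1103 of 23935 probe sets passed for drip loss in limma, 464 higher and 639 lower, and 4624 had an unadjusted p under 0.05 against 1196.8 expected without any relation. The passing probe sets with a single symbol numbered 515, and among them more rose than fell, as did 337 of the 514 genes that passed with 1 probe set per gene; the excess of decreases lay in probe sets without a single symbol. Of all tested probe sets 4.61% passed, and this became 0.623% with blocks in the fit, 0.831% without the 24 low-correlation arrays, 2.43% with the 3' to 5' signal difference of control transcripts as a covariate and 0.0543% with 5 principal components. Camera with its preset correlation called 11 lists, but it called a median of 5 when drip loss was shuffled among animals.

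For fat area, the comparison asked which muscle transcripts track carcass fatness, and the largest slope of any probe set with a single gene symbol was that of a Y-linked transcript. EIF1AY, a translation factor chosen for mention after its values were seen, rose by 0.73 ± 0.11 log2 per SD of fat area (SE, all animals with a fat area, limma adjusted p = 2.0e-05). Its values formed separate clusters of animals, described below, so this slope mainly reflects which cluster an animal belonged to and not a graded rise. The X-linked histone demethylase KDM6A fell by 0.14 ± 0.027 (adjusted p = 0.0010) and TXLNG by 0.097 ± 0.021 (adjusted p = 0.0085). Outside the sex chromosomes, the amidase NIT1 rose by 0.097 ± 0.018 (adjusted p = 4.1e-04). CPT1A, an enzyme of mitochondrial fatty acid import, fell by 0.13 ± 0.030 (adjusted p = 0.038, and 0.071 with blocks). The basement membrane collagen COL4A2 fell by 0.082 ± 0.019 (adjusted p = 0.026).

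Only 29 probe sets passed, 11 higher and 18 lower, while 1692 had an unadjusted p under 0.05 against 1196.8 expected. With a single symbol there were 13, for 12 genes. With 1 probe set per gene, 10 genes passed, 2 higher and 8 lower. The ubiquitin-conjugating enzyme UBE2E3 rose by 0.091 ± 0.022 (SE, adjusted p = 0.046; adjusted p = 0.087 with blocks). The deubiquitinase USP9X fell by 0.092 ± 0.021 and the junction protein JAM3 by 0.068 ± 0.016, both with an adjusted p of 0.028. A probe set for the complex I subunit NDUFA1 fell by 0.19 ± 0.046 (adjusted p = 0.032). The brighter probe set that stood for NDUFA1 in the gene lists did not pass, as 0 of 33 complex I subunits did. ZRSR2 and RBP7, both dim and outside the rule for named genes, fell by 0.083 ± 0.018 and 0.088 ± 0.020. Of probe sets listed under several gene models and also chosen after their values were seen, 1 for EIF2S3 rose by 0.97 ± 0.16 and another fell by 0.14 ± 0.028, 1 for TMSB4X rose by 0.77 ± 0.14 and 1 for DDX3X rose by 0.22 ± 0.045. EIF1AY formed 2 separate clusters, 92 animals between 4.00 and 4.66 and all others between 6.57 and 8.48. Its correlation with fat area over all animals is therefore not given. Inside them, r with fat area was 0.175 (permutation p = 0.0957) and 0.15 (permutation p = 0.125), and rho was 0.19 (permutation p = 0.0713) and 0.186 (permutation p = 0.0567). Among probe sets with 1 gene of known chromosome, 6 of the 12 that passed lay on X or Y (50%) against 331 of the 9834 others (3.37%, Fisher's exact test p = 1.2e-06, two-sided). The test takes probe sets as independent, which these are not. TXLNG was counted more than once, and 5 of the 6 had an absolute r above 0.4 with EIF1AY. With a covariate made from the measured Y-linked genes EIF1AY and SRY, 0 of 23935 probe sets passed in limma. Then 1165 had an unadjusted p under 0.05, and NIT1 kept a slope of 0.076 ± 0.019 (adjusted p = 0.846). The rising probe sets listed for EIF2S3, TMSB4X and DDX3X then had slopes of -0.021 ± 0.030, -0.087 ± 0.049 and 0.015 ± 0.034. The falling one for EIF2S3 had -0.014 ± 0.023. With EIF1AY the rising ones had an absolute r of 0.988, 0.952 and 0.765, and the falling one 0.729, so all of them followed EIF1AY. The several gene models of these probe sets leave open which transcript each measured, so the rises are not assigned to the named genes.

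**Figure D3:**
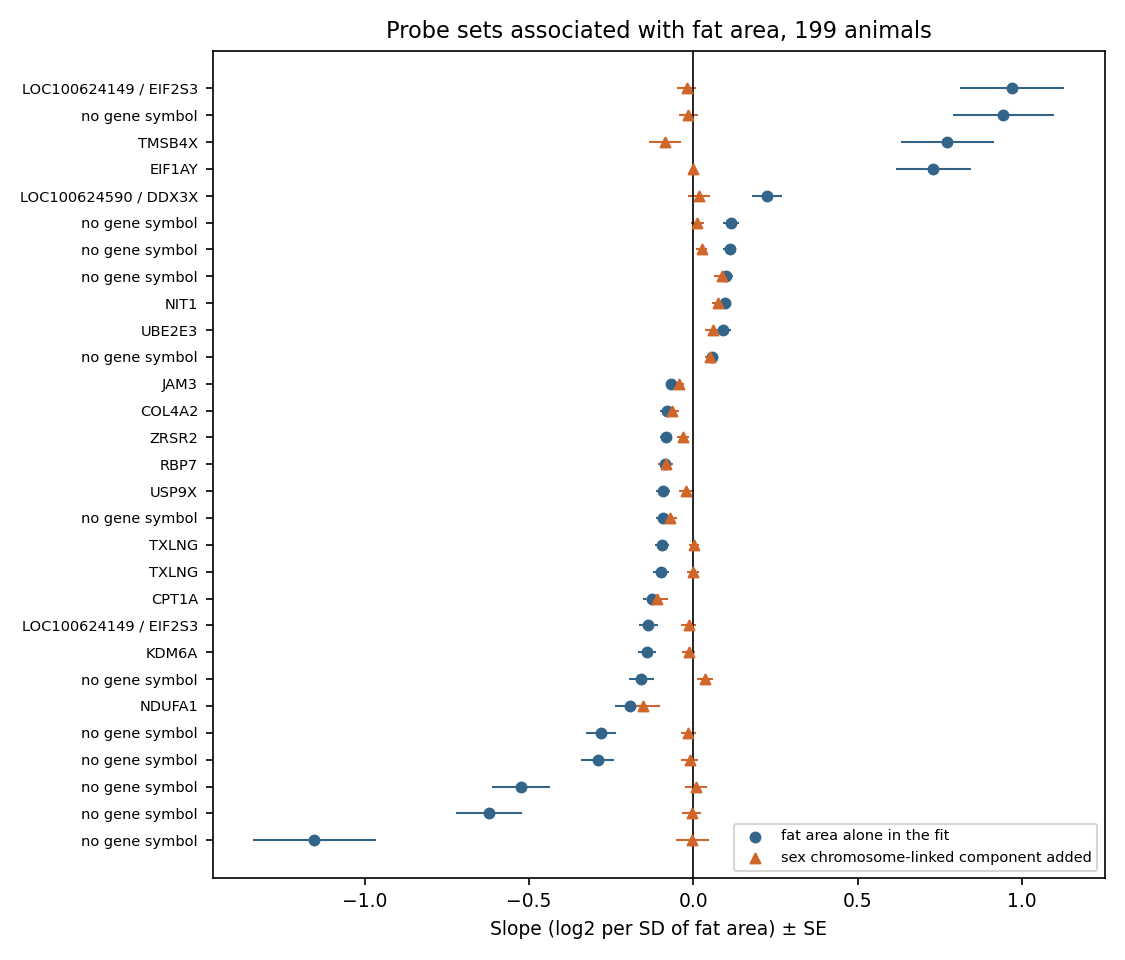
Slope on fat area, in log2 units per SD with bars of 1 SE, of the 29 probe sets that passed an adjusted p of 0.05 over all animals with a fat area, with fat area alone in the fit (circles) and with the sex chromosome-linked covariate added (triangles). The median absolute slope was 0.13 alone and 0.022 with the covariate.

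Gene groups moved little with fat area. Camera with the preset correlation called 3 lists upward and 2 downward, and with quantile normalization 1 upward and 2 downward. Of 16 endothelial and vascular smooth muscle markers 14 had negative slopes, 0 passed in limma over all genes and 3 fell when adjusted over the list alone, namely PECAM1 at -0.083 ± 0.021, CDH5 at -0.071 ± 0.020 and CLDN5 at -0.082 ± 0.031 (SE). Camera called the list with the preset correlation (adjusted p = 2.8e-05) and not with an estimated one (adjusted p = 0.185), and fry gave an adjusted p of 0.060. Fry called it with blocks in the fit (adjusted p = 0.020), where PECAM1 passed over all genes (adjusted p = 0.0245). Extracellular matrix was called downward (adjusted p = 0.0011, and 0.707 with an estimated correlation). COL4A2 was the 1 of 21 members that passed, with BGN at -0.094 ± 0.031 and COL6A2 at -0.039 ± 0.019. In the higher number series (n = 25) the slopes of extracellular matrix, COL4A2 and the endothelial list were positive, at 0.027, 0.035 and 0.024, and did not pass. Heat shock genes were called upward, with HSPE1 at 0.041 ± 0.013, HSPH1 at 0.14 ± 0.052 and HSP90AB1 at 0.037 ± 0.015, and 0 of 19 passed over all genes (adjusted p = 4.5e-06; adjusted p = 0.408 with an estimated correlation). Ribosomal proteins were called upward with 0 of 57 members passing, RPS19 at 0.016 ± 0.0086, RPS26 at 0.016 ± 0.0089 and RPL26 at 0.026 ± 0.014 (adjusted p = 2.8e-06; adjusted p = 0.915 with an estimated correlation). Fatty acid and triglyceride synthesis was called upward with 0 of 17 members passing and 15 positive slopes (adjusted p = 0.043; adjusted p = 0.707 with an estimated correlation and 0.0789 with blocks). In it, the desaturase SCD had a slope of 0.14 ± 0.084, FASN 0.089 ± 0.060, ME1 0.042 ± 0.021 and AGPAT2 0.032 ± 0.017. The adipocyte genes FABP4 (-0.025 ± 0.038) and ADIPOQ (0.0037 ± 0.034), and MYH7, PYGM, RYR1, PRKAG3 and CAST, with slopes from -0.0061 to 0.0054, did not pass either.

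The other 29 lists, adipocyte markers and complex I among them, were not called for fat area (camera adjusted p 0.0687 to 0.987; in 9 of them the camera direction, the median slope and the slope of the mean did not share a sign), and in 32 lists no member passed in limma over all genes. The exceptions were COL4A2 in extracellular matrix and CPT1A in fatty acid uptake and oxidation. Without the 13 arrays that lack spike-in signal neither passed (adjusted p = 0.062 and 0.084), nor did UBE2E3 (0.057), NDUFA1 and JAM3 (both 0.065). Without the 24 low-correlation arrays camera also called complex I (adjusted p = 0.032, 25 of 33 slopes negative), TCA cycle (0.032), fatty acid uptake and oxidation (0.0031) and interferon response (0.033) downward and circadian clock upward (0.023), none of them with an estimated correlation (adjusted p 0.067 to 0.963). Fry then called circadian clock (adjusted p = 0.028) and endothelial markers (adjusted p = 0.024). By rank, fat area correlated with the list means of circadian clock (rho = 0.229), endothelial and vascular smooth muscle markers (rho = -0.224) and water and ion transport (rho = -0.218), each with an adjusted permutation p of 0.0207 over 34 lists. Pearson's r was 0.191, -0.211 and -0.192, each with an adjusted permutation p of 0.0805. Without the 2 farthest animals it was 0.233, -0.212 and -0.196. With shuffled fat areas, camera with the preset correlation again called a median of 5 lists, as many as with the real values, and over all arrays 0 of the 34 lists were called with an estimated correlation or by fry, each of which gave 3 an unadjusted p under 0.05.

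The chemokine CXCL2 and the immediate early gene DUSP1 had different slopes on the 2 traits. Fitted together in the animals with both traits, CXCL2 had a slope of 0.036 on fat area and -0.30 on drip loss, each per SD, a difference of 0.33 ± 0.057 (SE, adjusted p = 5.2e-04), and FOS had 0.033 and -0.49, a difference of 0.52 ± 0.11 (adjusted p = 0.0065). DUSP1 differed by 0.29 ± 0.054, AZIN1, a regulator of polyamine synthesis, by 0.20 ± 0.040 and PAPD7 by 0.092 ± 0.021. In the other direction, ATP5I differed by -0.13 ± 0.027, ABHD10 by -0.10 ± 0.022, CIB1 by -0.10 ± 0.022, the import subunit TIMM17B by -0.087 ± 0.019 and the signalosome subunit COPS6 by -0.085 ± 0.017. In all, the difference between the slopes passed for 83 probe sets, 52 with the fat area slope above the drip loss slope and 31 below, and 3021 had an unadjusted p under 0.05. No probe set passed for both traits (0 shared, 1.34 expected from the numbers that passed), and the correlation of the slopes on both traits across probe sets, which are not independent replicates, was -0.061 against -0.099 ± 0.123 (SD) in shuffled data. With blocks in the fit 12 differences passed, 4 with the fat area slope above and 8 below, among them those of CXCL2, DUSP1, TIMM17B and COPS6. The differences of FOS, AZIN1, PAPD7, ATP5I, ABHD10 and CIB1 did not pass with blocks (adjusted p 0.0737 to 0.158). With 5 principal components 42 passed, 28 above and 14 below, among them those of CXCL2, DUSP1, AZIN1 and ATP5I.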

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

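The tests with the control signal difference and without the arrays lacking spike-in signal were chosen only after the data were seen. For drip loss, 4.61% of tested probe sets passed, and 0.623% did with blocks, 0.823% in the lower series of title numbers alone, 0 in the higher (limma, n = 33, 1789 with an unadjusted p under 0.05), 0.0543% with 5 principal components, 0.831% without the low-correlation arrays and 2.43% with the control signal difference; camera with an estimated correlation called 1 list against 11. Leaving out 24 random arrays gave a median of 3.02% (0.280% to 9.39% in 100 draws), so fewer arrays alone lowered the percentage in part. For fat area, 0.121% passed, and 0 did in the higher series (limma, n = 25, 978 with an unadjusted p under 0.05), 0.380% with principal components and 0 with the sex chromosome-linked covariate; the lists called were 3 with quantile normalization, 2 in the higher series, 10 without the low-correlation arrays, and 0 with an estimated correlation or by fry, against 5. The difference between the traits passed in 0.347% of probe sets, in 1.11% of those above the median signal, where fewer are tested, in 0.0501% with blocks and in 0.175% with principal components. Signs reversed for NDUFA1 (0.00094), COL4A2 (0.035), extracellular matrix (0.027) and endothelial markers (0.024) with fat area and for PRKAG3 (-0.020) with drip loss in the higher series, where few animals remain, for EIF1AY (-8.2e-05) and TXLNG (0.0014) with the sex chromosome-linked covariate, and for costamere genes (0.0011) and ribosomal proteins (-0.0060) with principal components. Lists called for drip loss kept direction and call in 78.9% of 209 results, and named genes in 80% of 670; for fat area these were 72.6% of 95 results of called lists and 78% of the results of called named genes. Where neither fewer animals nor a covariate built from the same genes accounts for a change, the cause was not tested. The log2(value + 1) alternative was not run. Signal near the floor limits dim probe sets such as ZRSR2, and camera with its preset correlation called as many lists as for drip loss in 9 of 100 shuffles and as for fat area in 52.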

Other observations

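Of the tests given here, the use of blocks of title numbers, themselves chosen beforehand, to weigh the patterns of 2 gene lists and of the fat area probe sets, the X and Y share of those probe sets, their slopes set against 50%, their division by EIF1AY, and the pairs of gene lists were chosen only after the result was seen.

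Across the 207 animals, list means moved together. Immediate early genes, heat shock genes, complex I and the proteasome were each also called by camera for drip loss. Relations among these lists may in part repeat that comparison, and none was computed with drip loss held fixed. Immediate early genes such as FOS and EGR1 and heat shock genes such as HSPH1 and BAG3 rose and fell together (r = 0.54, rho = 0.503), and immediate early genes ran against complex I (r = -0.356, rho = -0.391). Complex I went with the slow fibre list, which holds MYL2 and TNNT1 (r = 0.557, rho = 0.502), adipocyte markers such as FABP4 went with fatty acid and triglyceride synthesis genes such as SCD and FASN (r = 0.518, rho = 0.47), and macrophage markers went with extracellular matrix (r = 0.544, rho = 0.521). The permutation p of each of these was 1e-05, the smallest that the permutations can give, with adjusted values of 1.2e-05 for r and 1e-05 for rho over a family of 6. The remaining pair, complex I and the proteasome, had r = 0.26 (permutation p = 2.3e-04, adjusted p = 2.3e-04) and rho = 0.399 (permutation p = 1e-05). Without the 2 animals farthest from the median of the first list of each pair, and in the same order, r was 0.539, -0.351, 0.534, 0.466, 0.505 and 0.413. In the lower series of title numbers it was 0.525, -0.339, 0.546, 0.571, 0.57 and 0.263, in the higher series it was 0.606, -0.431, 0.611, 0.239, 0.227 and 0.30, and centred within blocks it was 0.538, -0.326, 0.512, 0.529, 0.547 and 0.261. Without the 24 low-correlation arrays it was 0.547, -0.356, 0.424, 0.653, 0.532 and 0.416.

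Random assignment of the traits tested the counts as a whole. For drip loss, 1 of 100 assignments, the real one, reached the 1103 probe sets, and the highest other gave 3. Within blocks of title numbers, again only the real one, 1 of 100, reached its own count, with 10 as the highest other. Both real counts for drip loss thus lay far above those of the random assignments drawn. With 100 assignments the share cannot fall below 1 of 100. Sire and slaughter day, which the labels do not give, could not be kept together in the shuffling. For fat area, 2 of 100 reached the 29 probe sets, the real one included, and the other one gave 72. The share is low, but a random assignment exceeded the real count, so chance cannot be excluded by this test. The 29 are also not independent, since 19 of them had an absolute r above 0.4 with EIF1AY and tend to pass together.

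Immediate early genes were lower at higher drip loss, with a list mean slope of -0.209 log2 per SD (SE 0.033, n = 207). The tables argue against 3 explanations as the whole cause, as far as the measures used here capture them. The 95% interval of the slope stayed beyond 50% of this value with each measure in the fit. An imperfect measure removes only part of what it stands for, so a part played by each stays open. The slope was -0.199 (-0.267 to -0.132) with blocks of title numbers, -0.202 with the control signal difference as a measure of RNA integrity, and -0.22 with the means of endothelial, macrophage and blood cell markers. Handling before slaughter and the time from death to sampling, which could act on rapidly induced genes such as FOS and DUSP1, are not given in the sources used here and stay open. The labels name no group that offers a biological explanation, so apart from the cell content of the piece none was weighed by the slope of the list mean. As single covariates, the sex chromosome-linked component, fat area and the adipocyte marker mean each left the calls of the 42 named genes for drip loss in place.

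Complex I genes were higher at higher drip loss, with a list mean slope of 0.043 (SE 0.010). With the control signal difference in the fit the slope was 0.0424 (interval 0.0224 to 0.0624). The lower end lay only just above 50% of the value without it (0.0216). RNA integrity as far as these control transcripts measure it is therefore an unlikely cause of the whole pattern, and a part played by it stays open. Differences between blocks of title numbers cannot be told apart from the trait here, since the slope was 0.0318 with blocks and its interval of 0.0118 to 0.0518 reached below 50% of the value without them. The share of slow fibres may also contribute and cannot be told apart either (0.0365, interval 0.0200 to 0.0530). Array quality stays open as well, since without the 24 low-correlation arrays the slope was 0.027 (SE 0.0081).

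Many probe sets associated with fat area may reflect a difference between females and males, which the labels do not name. With the covariate made from EIF1AY and SRY, 0 of the 29 kept their call as the median absolute slope went from 0.13 to 0.022 (median SE 0.027 and 0.023). EIF1AY is itself 1 of the 29, and 19 of them, itself included, had an absolute r above 0.4 with it. For those the covariate largely sets the outcome, so their loss is not separate support. Genes on X or Y were overrepresented among those that passed (Fisher's exact test p = 1.19e-06), but this test takes correlated probe sets as independent. Taken singly, the 95% interval of the slope with the covariate lay under 50% of the slope without it for 16 of the 29, KDM6A and TXLNG among them, above it for 0, and across it for 13, NIT1, COL4A2 and CPT1A among them, so for these a difference between females and males cannot be told apart from fat area. Divided at an absolute r of 0.4 with EIF1AY, 19 probe sets kept a median of 0.963% of their slope and the other 10 kept 78.99%, but the division largely sets these shares and they decide nothing. Blocks of title numbers are an unlikely cause of the whole pattern, since 26 of the 29 kept their call with blocks in the fit, CPT1A, UBE2E3 and 1 probe set without a symbol being the exceptions.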
